A study of Mus musculus with 31 samples.

How the data were processed

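RNA of bone-marrow macrophages was measured on 31 spotted arrays, each holding a stimulated sample and a mock sample in the 2 dyes. The groups, taken from the labels, are wild-type LPS, MyD88-/- LPS, wild-type E. coli and MyD88-/- E. coli, with 4 mice each, and 0 columns were left unmapped. The authors scanned the slides and quantified them with GenePix software and analysed them in BASE and GeneSpring, per the labels. The deposited values are log2 ratios of the channels of an array, as the authors normalized them. The labels do not state the background correction, the normalization, the spot filter or the direction of the ratio. Column medians lay between -0.122 and 0.0794 and median absolute deviations between 0.346 and 0.676. Of 13872 probes 2842 had a value on all 31 arrays and 426 on none.

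Direction was checked on the 15 pairs of arrays of 1 mouse and stimulus with swapped dyes. All 15 correlated above 0 across probes, with r between 0.185 and 0.629 as deposited and between 0.256 and 0.71 without values at the floor, so the arrays run the same way and none was turned. Reading the ratio as stimulated over mock follows the titles and the rise of textbook LPS genes, and is called likely. A floor of log2(0.01), -6.64, held 4333 of 265421 values (1.63%), 2982 of them on swapped arrays and 1351 on unswapped arrays. In 1773 cases the partner array had a value, with a median of -0.107, so values at the floor were treated as missing, a step that the design set before the data were examined did not foresee. Between pairs this median ranged from -0.898 (171 cases, wild-type E. coli mouse 1) to 0.138. It was -0.409 in MyD88-/- E. coli mouse 2, so in these 2 mice some values at the floor may stand for falls. The arrays of a mouse and stimulus were averaged, giving 16 mouse-level ratios.

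Probes with a value in at least 3 of the 4 mice of every group were tested, 7325 of 13872. A linear model with 1 coefficient per group was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, prior degrees of freedom 2.97), and p were adjusted by Benjamini and Hochberg over the probes tested, with a call at an adjusted p under 0.05. The 9 comparisons are the 4 responses, the genotype difference for each stimulus, the stimulus difference within each genotype and their interaction. Probes called in a wild-type response were also tested for the genotype difference with adjustment over those probes alone. All p are 2-sided. The error of a fitted value is the standard error of limma. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.

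Symbols come from the table that pairs probes and genes. Of 13872 probes 11480 had 1 symbol, 50 several and 2342 none, and 11437 of the 11480 matched a current gene by Entrez ID, with 0 symbols changed. Named genes follow a rule set before the values were seen. For each response it takes the 12 largest rises and 8 largest falls among called probes of 1 sign in every mouse measured. For each difference it takes the 10 largest in each direction among called probes whose mouse values do not overlap, and for the interaction 5 in each direction. It adds the 4 members of smallest p of each list in each comparison and 21 fixed genes, Myd88 among them. A gene with several probes is represented by the probe with values on most arrays, and genes named outside the rule are said to be so. Several probes of a gene can disagree, as for Il1b, whose second probe (11722) gave -0.525, -0.302, -0.359 and -0.178 in the 4 groups in the order above.

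The 23 gene lists were written before the data were examined. They hold proinflammatory cytokines, chemokines, interferon and interferon-stimulated genes, the NF-kB pathway and feedback, immediate early and MAPK feedback genes, Toll-like receptor pathway components, antimicrobial and inflammatory effectors, antigen presentation, oxidative stress, cell cycle, sterol and lipid metabolism, glycolysis and hypoxia, lysosome and phagocytosis, cell death, macrophage identity, ribosomal proteins and housekeeping genes. Markers of T cells, B cells, neutrophils, dendritic cells, erythroid cells and stromal cells form the other lists. Each was tested with cameraPR in limma on the moderated statistic, with 1 probe per gene, a preset correlation of 0.01 and adjustment over the 23 lists of a comparison, and again with a correlation estimated from residuals. A list's p in the text is the adjusted p with the preset correlation unless an estimated correlation is named. Of 207 list tests 59 were called with the preset and 44 with the estimated correlation. List means per mouse were compared by a 2-sided exact permutation test, 4 mice against 4, whose smallest p is 0.029.

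The labels give the same mouse numbers to both stimuli within a genotype, so the mouse as a block was an alternative for comparisons between stimuli. Residuals of the same number correlated between -0.057 and 0.14, and were the best match in 2 of 8 cases. Alternatives set before the values were seen were centring or scaling each array, other filters on missing values, a dye term with a random block, unswapped arrays alone, another variance prior, a fit on the groups of a comparison alone, a change of at least 2-fold, the mean over all probes of a gene, the estimated correlation and leaving out each mouse in turn. Leaving out each mouse was set beforehand for probe counts and named genes, and was added for lists after the data were seen. Other alternatives chosen after the data were seen are named as such with their values. The fit was tested on simulated data with the missing values and spreads of the 7325 probes, changing 67, 67 and 66 probes by 1, 2 and 3 on the log2 scale in 1 group. It recovered 61.2%, 94% and 100% of these in the wild-type LPS response, with 9 false calls of 179, and 37.3%, 83.6% and 87.9% in the LPS genotype difference, with 5 false calls of 144. Il6, Il12b, Ptgs2, Nos2, Nfkbia and Cd14 of the fixed genes had too few values to be tested in the 4 groups together.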

Results

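The series holds 31 spotted arrays, each pairing RNA of stimulated macrophages with RNA of macrophages given medium alone (mock). Macrophages were grown for 8 days from the bone marrow of C57BL/6J wild-type mice and of mice lacking MyD88, the adaptor through which most Toll-like receptors signal, and were stimulated for 2 hours. The stimulus was re-purified LPS, the Gram-negative outer-membrane lipid, at 10 ng/mL, or live E. coli at 1 bacterium per macrophage. Each of the 4 groups of genotype and stimulus holds 4 mice, and each mouse and stimulus has an array in both dye orientations except MyD88-/- LPS mouse 4, which has 1 array. Values are the authors' log2 ratios, read here as stimulated over mock, which is likely but not stated in the labels. An array carries between 5564 and 10497 values for 13872 probes, and 7325 probes, which stand for 5954 named genes, had enough values to be tested. The number of arrays limits the precision, and the median standard error of a response was between 0.202 and 0.205 on the log2 scale.

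Myd88 was measured in both genotypes. Its probe (12197) rose with LPS in wild-type cells, with a log2 ratio of 1.38 ± 0.42 (SE, n = 4 mice, adjusted p = 0.0346), and in MyD88-/- cells, with 2.16 ± 0.42 (adjusted p = 0.00293). With E. coli it rose in wild-type cells, by 1.48 (adjusted p = 0.0198), and gave 1.29 in MyD88-/- cells (adjusted p = 0.0658). All 16 mouse-level ratios were above 0, and the genotypes differed by 0.78 for LPS (adjusted p = 0.742) and by -0.19 for E. coli (adjusted p = 0.937). A ratio to mock cells of the same genotype does not measure the level of the message, and the position of the probe relative to the disrupted part of the gene is not known, so these values do not check the genotype. The wild-type LPS call ended without any 1 of wild-type LPS mice 1 to 4 (adjusted p between 0.0701 and 0.121) and the wild-type E. coli call without wild-type E. coli mouse 1, 2 or 3 (0.0523 to 0.0866), while the MyD88-/- E. coli value passed without MyD88-/- LPS mouse 4 (0.000333) or mouse 3 (0.049).

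The wild-type LPS arrays ask which messages LPS changed within 2 hours when MyD88 was present. Inflammatory cytokines and chemokines made up most of the largest rises. Il1b (probe 10766) had a log2 ratio of 6.19 ± 0.65 (SE, n = 4 mice, adjusted p = 6.37e-06), its partner cytokine Il1a 5.50 ± 0.42 (adjusted p = 2.79e-07) and Tnf 5.12 ± 0.21 (adjusted p = 8.48e-10). The neutrophil attractants Cxcl1 and Cxcl2 rose by 5.76 ± 0.44 and 4.88 ± 0.21 (adjusted p = 2.54e-07 and 8.48e-10), and Acod1, the enzyme that makes itaconate, by 4.84 ± 0.19 (adjusted p = 8.48e-10). Txnip, which binds thioredoxin and restrains glucose uptake, fell most among the named genes, to -4.15 ± 0.32 at probe 13525 and -3.74 at probe 6185, followed by the haematopoietic transcription factor Lyl1 at -3.54 and the cannabinoid receptor Cnr2 at -3.43.

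Of 18 cytokines on the array 7 had enough values to be tested. All 7 rose in wild-type cells given LPS, 7 also when adjusted over the list alone. Among them were the anti-inflammatory Il10 (4.52) and the interleukin 1 receptor antagonist Il1rn (2.91). Of 14 chemokines, 10 rose and 1 fell, with the same counts adjusted over the list alone. Ccl3, Ccl4, Ccl17 and Ccl2 rose by 4.31, 4.58, 3.74 and 3.25, and Cxcl14 fell to -1.16. Of 21 genes of the NF-kB pathway and its feedback, 18 rose (19 rose and 1 fell adjusted over the list alone), among them the inhibitor Tnfaip3 (4.27 ± 0.48, adjusted p = 1.3e-05), the adaptor Traf1 (2.96) and the subunit Relb (2.31). Of 46 interferon and interferon-stimulated genes, 20 rose and 1 fell (25 and 3 adjusted over the list alone), led by the chemokines Cxcl10 (4.70) and Ccl5 (3.93) and the transcription factor Irf1 (3.61). Ifnb1 itself gave 0.70 (adjusted p = 0.11) and Irf7 0.13 (adjusted p = 0.771). Of 26 immediate early and MAPK feedback genes, 14 rose and 4 fell (18 and 4 adjusted over the list alone), with Egr2 at 3.82, Gadd45b at 3.52, Egr1 at 0.88 and Fos, which was not called, at -0.70 (adjusted p = 0.163). Of 20 antimicrobial and inflammatory effectors, 11 rose (14 adjusted over the list alone), including the acute-phase gene Saa3 (4.33) and the lectin receptor Clec4e (3.72).

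Those 6 lists were shifted upward against all other genes, with adjusted p of 2.44e-26 for cytokines, 1.52e-22 for chemokines, 1.2e-35 for NF-kB, 3.03e-12 for interferon, 2.56e-07 for immediate early genes and 7.71e-18 for effectors. Each held with an estimated correlation, the interferon list at adjusted p = 0.0288. Of 24 Toll-like receptor pathway components, 5 rose and 1 fell, also adjusted over the list alone, with Tlr2 at 2.49 and Tlr1 at 1.67. That list passed at 0.0234, and gave an adjusted p = 0.126 with an estimated correlation. In all, 1247 of 7325 probes were called for wild-type LPS, 585 higher and 662 lower. The majority turned to the higher side with each array centred (643 and 581) or also scaled (602 and 524), at 2-fold or more (327 and 153), and without wild-type LPS mouse 1 (453 and 448) or 4 (516 and 492). A fit on the wild-type LPS mice alone called 653, 353 of them higher, or 375 with its own filter on missing values, 246 of them higher.

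The MyD88-/- LPS arrays ask what LPS still changed without MyD88. Interferon-related and NF-kB genes stood among the largest rises, beside Acod1, which rose by 5.46 (n = 4 mice). Cxcl10 rose by 5.35 (adjusted p = 9.65e-09), Irf1 by 4.33, Ccl5 by 4.21, the antiviral genes Ifit1 and Rsad2 by 4.02 and 3.92 (adjusted p = 0.000259 and 4.16e-05), and Traf1 and Relb by 3.93 and 3.36. Tnf also rose, by 3.59 (adjusted p = 3.57e-08), as did Cxcl1 (4.76), Il1a (3.30), Cxcl2 (2.38) and the costimulatory ligand Icosl (4.08). Ccl17 stood at -0.10 (adjusted p = 0.91), Plaur, the urokinase receptor, at 0.26 (adjusted p = 0.244) and Txnip (probe 13525) at -0.57 (adjusted p = 0.251). Cnr2 fell to -4.18 and the orphan receptor Gpr146 to -2.82.

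All 7 cytokines tested, of 18 on the array, rose in MyD88-/- cells given LPS (7 adjusted over the list alone). The limma call of Il10 ended without MyD88-/- LPS mouse 2 or 3 (adjusted p = 0.175 and 0.207). The filter needs values in every group, so cytokine genes with few values in MyD88-/- cells, such as Il6, were left out beforehand. Of 14 chemokines 8 rose and 1 fell (8 and 1 adjusted over the list alone). Of 46 interferon genes, 24 rose and 1 fell (28 and 1 adjusted over the list alone), and 18 of 21 NF-kB genes rose (19 adjusted over the list alone). Of 20 effectors, 9 rose (10 adjusted over the list alone), and of 26 immediate early genes 8 rose and 5 fell, also adjusted over the list alone. The shifts had adjusted p of 9.17e-17 for cytokines, 2.35e-09 for chemokines, 1.04e-27 for interferon, 4.55e-49 for NF-kB and 1.87e-16 for effectors, and all held with an estimated correlation. The immediate early list gave 0.0555, and an adjusted p = 0.0475 with an estimated correlation. It also passed, at 0.0305 to 0.0484, without wild-type LPS mouse 3, MyD88-/- LPS mouse 4, wild-type E. coli mouse 1, 2 or 3, or MyD88-/- E. coli mouse 2 or 4. Of 24 Toll-like receptor components, 5 rose (6 adjusted over the list alone), and the list passed at 0.000217 and 0.0205, preset and estimated. The count was 731 probes, 387 higher and 344 lower, and a fit on the MyD88-/- LPS mice alone called 417, or 255 with its own filter.

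The difference between the genotypes asks which part of the LPS response differed without MyD88. Of the 10 largest negative differences among called probes of named genes, 4 were those of chemokines. Ccl17, which attracts T cells, differed by -3.84 ± 0.51 (SE, n = 4 mice per genotype, adjusted p = 0.00164), Cxcl2 by -2.51 ± 0.30 (adjusted p = 0.000778), and the monocyte attractants Ccl7 and Ccl2 by -2.38 ± 0.35 and -2.29 ± 0.35 (adjusted p = 0.00428 and 0.00561). Cebpd, a transcription factor of the acute-phase response, rose by 1.29 in wild-type cells and fell to -1.18 in MyD88-/- cells, a difference of -2.47 ± 0.25 (adjusted p = 0.000212). Plaur differed by -1.58 ± 0.18, the kinase gene Plk2 by -1.67 and the deadenylase relative Noct (probe 2736) by -2.41. Prpf8, a core protein of the spliceosome, rose by 2.92 in wild-type cells and differed by -2.29 ± 0.20 (adjusted p = 7.55e-05). In the other direction, the fall of Txnip was smaller without MyD88, by 3.58 ± 0.42 at probe 13525 (adjusted p = 0.00108) and 2.81 ± 0.43 at probe 6185, and the transcription factor Klf10 fell to -1.33 in wild-type cells with a difference of 1.62 ± 0.21. The mouse values of the genotypes did not overlap for these genes, which the rule that picked them requires, nor for any of the 21 called probes.

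Cytokines, chemokines and immediate early genes were lower as groups in the LPS genotype difference, with adjusted p of 1.61e-06, 1.48e-11 and 6.01e-06, which held with an estimated correlation. Of 7 cytokines none was called (5 were lower adjusted over the list alone), while Tnf stood at -1.52 ± 0.30 (adjusted p = 0.05, passing at 0.0319, 0.0326 and 0.0446 without wild-type LPS mouse 2, wild-type E. coli mouse 2 and MyD88-/- E. coli mouse 1) and Il1b at -2.48 ± 0.92 (adjusted p = 0.424). Of 14 chemokines 4 were lower (6 lower and 1 higher adjusted over the list alone), and of 26 immediate early genes none was called (5 were lower adjusted over the list alone). Interferon genes were higher as a list (adjusted p = 0.00164), with no member called in either count, as for Ifit1 at 2.14 (adjusted p = 0.477), Rsad2 at 2.15 and Cxcl10 at 0.65, but the list gave an adjusted p = 0.409 with an estimated correlation and 0.0644 without MyD88-/- LPS mouse 2. The NF-kB list was not called, and Tnfaip3, Traf1, Tlr2 and Acod1 were not called in this difference. Markers of B cells were lower (adjusted p = 0.0164, and 0.0158 with an estimated correlation, 0.0644 without MyD88-/- LPS mouse 2), with 2 of 8 genes lower adjusted over the list alone, beside these groups. Oxidative stress genes (0.0164, and 0.015 with an estimated correlation) and cell cycle genes (0.00643, but adjusted p = 0.1 with an estimated correlation) were higher as lists. No member of these was called, also adjusted over the list alone. Effectors were lower at 0.0495, with an adjusted p = 0.097 with an estimated correlation. Their median was 0.0145 against a mean of -0.254, so the signs of median and test differ, and the call ended without any 1 of 9 mice, namely wild-type LPS mice 1 and 3 (0.108 and 0.192), MyD88-/- LPS mice 1, 2 and 4 (0.207, 0.0892 and 0.0693), wild-type E. coli mice 1, 3 and 4 (0.0548, 0.0514 and 0.0651) and MyD88-/- E. coli mouse 2 (0.0531).

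In all, 21 probes differed between genotypes for LPS, 16 lower and 5 higher in MyD88-/- cells. Tested among the 1247 probes of the wild-type LPS response alone, 66 differed (5.29%). Of these, 62 had a smaller or turned change without MyD88 and 4 a larger change. Picking probes by their wild-type values favours this direction, and among the 731 probes of the MyD88-/- response, a sort added after the data were seen, 47 differed, 24 with a larger change in MyD88-/- cells and 23 with a smaller or turned one. The 4 were the transcription inhibitors Id1 and Id2, which fell to -1.84 and -0.58 in wild-type and to -3.28 and -1.51 in MyD88-/- cells, the interferon-stimulated Cmpk2 (1.08 against 3.00) and an unnamed probe, all picked after their values were seen. Over the probes picked in wild-type cells, the median rise was 1.11 there and 0.73 in MyD88-/- cells, and the median fall -0.695 and -0.409. Over those picked in MyD88-/- cells it was 1.21 there and 1.12 in wild-type cells, and the fall -0.775 and -0.729, so the gap was wider for the wild-type picks, a difference that was not tested. Of the 1247 probes 554 were also called in MyD88-/- cells (44.4%), a count that does not test a difference. The 21 became 42 with a dye term and a random block and 12 on unswapped arrays alone, where Ccl17 (adjusted p = 0.206), Ccl2 (0.327), Noct and Txnip (probe 6185) (0.056 each) lost their calls, and scaling the arrays ended those of Cxcl2 (0.0603) and Noct (0.059). The 66 fell to 40 without MyD88-/- LPS mouse 4 and to 41 without mouse 1, and without mouse 4 Il1b and Ccl3 passed over all probes, with -3.64 (adjusted p = 0.016) and -3.26 (adjusted p = 0.000479).

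The wild-type E. coli arrays ask which messages live bacteria changed. Cytokines and chemokines made up most of the largest rises, as with LPS, and no single gene was called in the test between the stimuli. Il1b (probe 10766) rose by 7.86 (n = 4 mice, adjusted p = 3.84e-07), Il1a by 6.66, Tnf by 6.18 (adjusted p = 7.37e-11), Cxcl1 by 6.72, Ccl17 by 6.20 (adjusted p = 1.05e-08), Cxcl2 by 5.68 (adjusted p = 9.38e-11) and Cxcl10 by 6.34. The secreted amino acid oxidase Il4i1 rose by 5.43, the collagenase Mmp13 by 4.97 and Ifnb1 by 1.75 (adjusted p = 0.000381). Cnr2 and Lyl1 fell to -3.23 and -2.94, the glucocorticoid-induced Tsc22d3 to -2.87 and Txnip to -3.08 at probe 13525.

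All 7 cytokines rose in wild-type cells given E. coli (7 adjusted over the list alone), as did 10 of 14 chemokines (10 adjusted over the list alone), while 19 of 21 NF-kB genes rose and 1, the kinase subunit Ikbkg (-0.59), fell (19 and 2 adjusted over the list alone). Of 46 interferon genes 31 rose and 1 fell (34 and 2 adjusted over the list alone), with Ccl5 at 5.05, Mx2 at 3.77 and Ifit1 at 3.32. Of 26 immediate early genes 17 rose and 4 fell (20 and 5 adjusted over the list alone), with Gem at 5.11 and Egr2 at 5.02, and 11 of 20 effectors rose (13 adjusted over the list alone). The adjusted p were 3.28e-32 for cytokines, 7.31e-31 for chemokines, 1.9e-35 for NF-kB, 3.38e-21 for interferon, 2.8e-11 for immediate early genes and 3.06e-21 for effectors, all held with an estimated correlation. Of 24 Toll-like receptor components 7 rose and 1 fell (7 and 2 adjusted over the list alone), and that list passed at 0.0347, but gave an adjusted p = 0.168 with an estimated correlation and 0.0854 without wild-type E. coli mouse 2. The count was 1554 probes, 691 higher and 863 lower, and a fit on the wild-type E. coli mice alone called 848, 470 of them higher, or 587 with its own filter, 358 of them higher. At 2-fold or more the majority also turned (352 higher and 209 lower).

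The MyD88-/- E. coli arrays ask what bacteria changed without MyD88. Interferon-related and NF-kB genes again stood among the largest rises, with Cxcl10 at 5.81 (n = 4 mice), Acod1 at 5.31, Rsad2 at 4.31, Ccl5 at 4.24, Irf1 at 4.23, Ifit1 at 4.07 and Traf1 at 3.68. Cxcl1 rose by 4.60, Tnf by 3.93 (adjusted p = 1.62e-08), the fatty acid receptor Gpr84 by 4.25 and the adhesion molecule Vcam1 by 4.49. Ccl17 stood at 0.40 (adjusted p = 0.593), Ccl3 at 1.03 (adjusted p = 0.115, but 0.00649 without MyD88-/- LPS mouse 4), Ccl7 at -0.02 and Ifnb1 at 0.26 (adjusted p = 0.674). Pparg, a nuclear receptor of lipid metabolism, fell to -2.19, the signal regulator Rgs2 to -2.50 and Id1 to -3.08.

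In MyD88-/- cells given E. coli all 7 cytokines tested (7 adjusted over the list alone), 7 of 14 chemokines (8 rose and 1 fell adjusted over the list alone), 18 of 21 NF-kB genes (18 and 1) and 9 of 20 effectors (11) rose. The limma call of Il10 ended without MyD88-/- E. coli mouse 3 or 4 (adjusted p = 0.0786 and 0.0681). Of 46 interferon genes 31 rose and 1 fell (34 and 1 adjusted over the list alone). Their shifts had adjusted p of 1.89e-15, 4.19e-09, 9.21e-44, 4.29e-17 and 1.08e-36 in that order, all held with an estimated correlation. Of 26 immediate early genes 9 rose and 6 fell (10 and 7 adjusted over the list alone), with no shift of the list (adjusted p = 0.436, and 0.452 with an estimated correlation). Of 24 Toll-like receptor components 5 rose (6 rose and 1 fell adjusted over the list alone), and the list passed at 0.00522, but gave an adjusted p = 0.0792 with an estimated correlation. Of 4 T cell markers 2 fell beside these groups, Cd28 (-1.25) and the interleukin 7 receptor gene Il7r (-0.86), and the list passed at 0.00371, and 0.00365 with an estimated correlation. The count was 789 probes, 465 higher and 324 lower. It was 510 without MyD88-/- E. coli mouse 2, and a fit on the MyD88-/- E. coli mice alone called 436, or 276 with its own filter.

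The genotype difference for E. coli asks which part of the response to live bacteria differed without MyD88. Chemokines and cytokines made up most of the largest called differences, with smaller rises in MyD88-/- cells. Ccl17 differed by -5.80 ± 0.51 (SE, n = 4 mice per genotype, adjusted p = 1.45e-05), Ccl3 by -4.37 ± 0.55 (adjusted p = 0.00059), Il1a by -3.72 ± 0.60 (adjusted p = 0.00546), Cxcl2 by -3.39 ± 0.30 and Ccl2 by -3.28 ± 0.35 (adjusted p = 1.45e-05 and 0.000124), Cebpd by -3.00 ± 0.25 (adjusted p = 1.45e-05) and Tnf by -2.25 ± 0.30 (adjusted p = 0.00105). Il1b differed by -4.90 ± 0.92 (adjusted p = 0.0176). Txnip differed in the other direction, by 2.95 ± 0.47 at probe 6185 and 2.68 ± 0.39 at probe 13525, and so did Klf10 by 1.82 ± 0.21, the cohesin acetyltransferase gene Esco2 by 1.53 ± 0.26 and Trim59 by 1.30 ± 0.19. The mouse values of the genotypes did not overlap for these genes, nor for any of the 55 called probes, and the rule for the largest differences requires this.

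Of 7 cytokines 4 were lower without MyD88 in the E. coli response (6 adjusted over the list alone), of 14 chemokines 6 (7), of 26 immediate early genes 4 (16), with Junb at -1.06 (adjusted p = 0.00745), and of 20 effectors 3 (5), with Saa3 at -2.21 (adjusted p = 0.000806). The adjusted p of these lists were 2.15e-15, 6.54e-23, 6.45e-17 and 0.000221, and all 4 held with an estimated correlation. The interferon and NF-kB lists were not called. Of 46 interferon genes 1 was lower, the signalling inhibitor gene Socs1 at -2.52 (adjusted p = 0.0405), and 3 were higher and 4 lower adjusted over the list alone, while of 21 NF-kB genes none was called (2 lower adjusted over the list alone). The Socs1 call held only without wild-type E. coli mouse 4 or wild-type LPS mouse 1 or 2, and ended without any other mouse (adjusted p between 0.0513 and 0.13). Cxcl10 (-0.53, adjusted p = 0.594), Ccl5 (-0.80, adjusted p = 0.267), Ifit1 (0.75, adjusted p = 0.759) and Tlr2 (0.85, adjusted p = 0.142) were not called, but the NF-kB list passed without wild-type E. coli mouse 1 (0.0148), wild-type E. coli mouse 4 (0.0214) or MyD88-/- E. coli mouse 2 (0.0144). Per mouse, the mean log2 ratio of the chemokines was 3.10 ± 0.35 (SD, n = 4) in wild-type and 1.20 ± 0.20 in MyD88-/- cells, and that of the NF-kB genes 2.27 ± 0.25 and 1.99 ± 0.20 (exact 2-sided permutation p = 0.0286 and 0.171). For LPS the chemokine means were 2.38 ± 0.21 and 1.26 ± 0.30 (exact permutation p = 0.0286), the cytokine means, which overlapped at 3.71 in wild-type mouse 2 and 3.72 in MyD88-/- mouse 4, 4.09 ± 0.33 and 2.77 ± 0.78 (exact permutation p = 0.0571), and the interferon means 1.11 ± 0.27 and 1.5 ± 0.27 (exact permutation p = 0.114). The smallest p such a test can give is 0.0286, which 4 of 23 lists reached for LPS and 6 for E. coli, and after adjustment over lists the lowest exact p was 0.16 and 0.11.

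**Figure D1:**
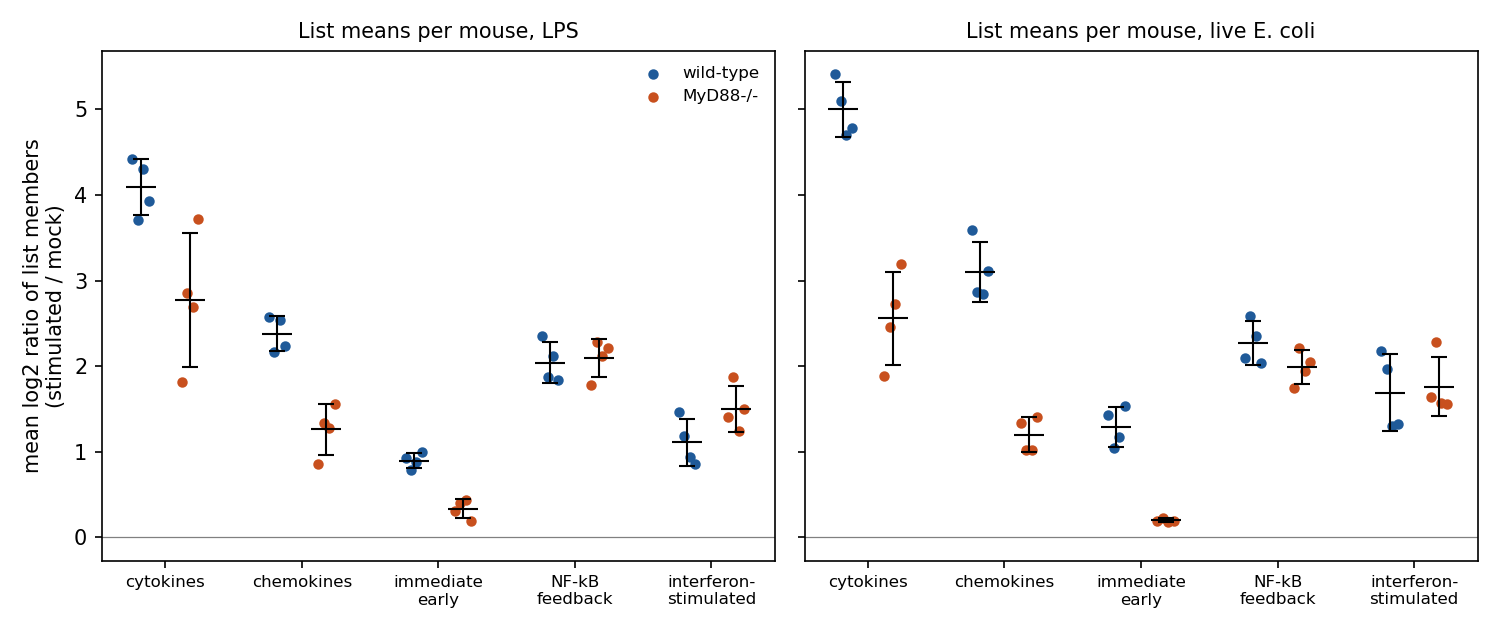
Mean log2 ratio, stimulated over mock, of the genes of 5 lists in each mouse (points), by genotype and stimulus, with bars for the mean and its SD over 4 mice. Chemokine means lie at 2.38 and 3.10 in wild-type and at 1.26 and 1.20 in MyD88-/- cells for LPS and E. coli.

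In all, 55 probes differed between genotypes for E. coli, 40 lower and 15 higher in MyD88-/- cells, and they include all 21 probes of the LPS difference in the same direction. Among the 1554 probes of the wild-type E. coli response alone, 228 differed (14.7%). Of these, 220 had a smaller or turned and 8 a larger change without MyD88, a direction that picking by wild-type values favours. Among the 789 probes of the MyD88-/- response 87 differed, 38 with a larger and 49 with a smaller or turned change in MyD88-/- cells. The 8 include Id1, Id2, Vcam1 and Tlr2, picked after their values were seen. The median rise was 1.01 in wild-type and 0.64 in MyD88-/- cells over the wild-type picks, and 1.04 and 1.11 over the MyD88-/- picks, and the median fall was -0.718 and -0.325 and then -0.791 and -0.787. Without wild-type E. coli mouse 1 the 55 became 35, ending the call of Ccl4 (adjusted p = 0.0597), and without MyD88-/- E. coli mouse 1 they became 36, the 228 became 134, 139 and 146 without MyD88-/- E. coli mice 4, 1 and 2, and the call of Il1b ended without wild-type E. coli mouse 1 or 2 or MyD88-/- E. coli mouse 1 or 2 (adjusted p between 0.0584 and 0.0666). The balance was closer to even with a dye term and a random block (189 probes, 83 higher and 106 lower) and over probes with a value on all arrays (126, 54 higher and 72 lower). The 55 became 24 on unswapped arrays alone, where Il1b, Tnf, Ccl4, Saa3, Junb and Txnip (probe 13525) lost their calls.

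**Figure D2:**
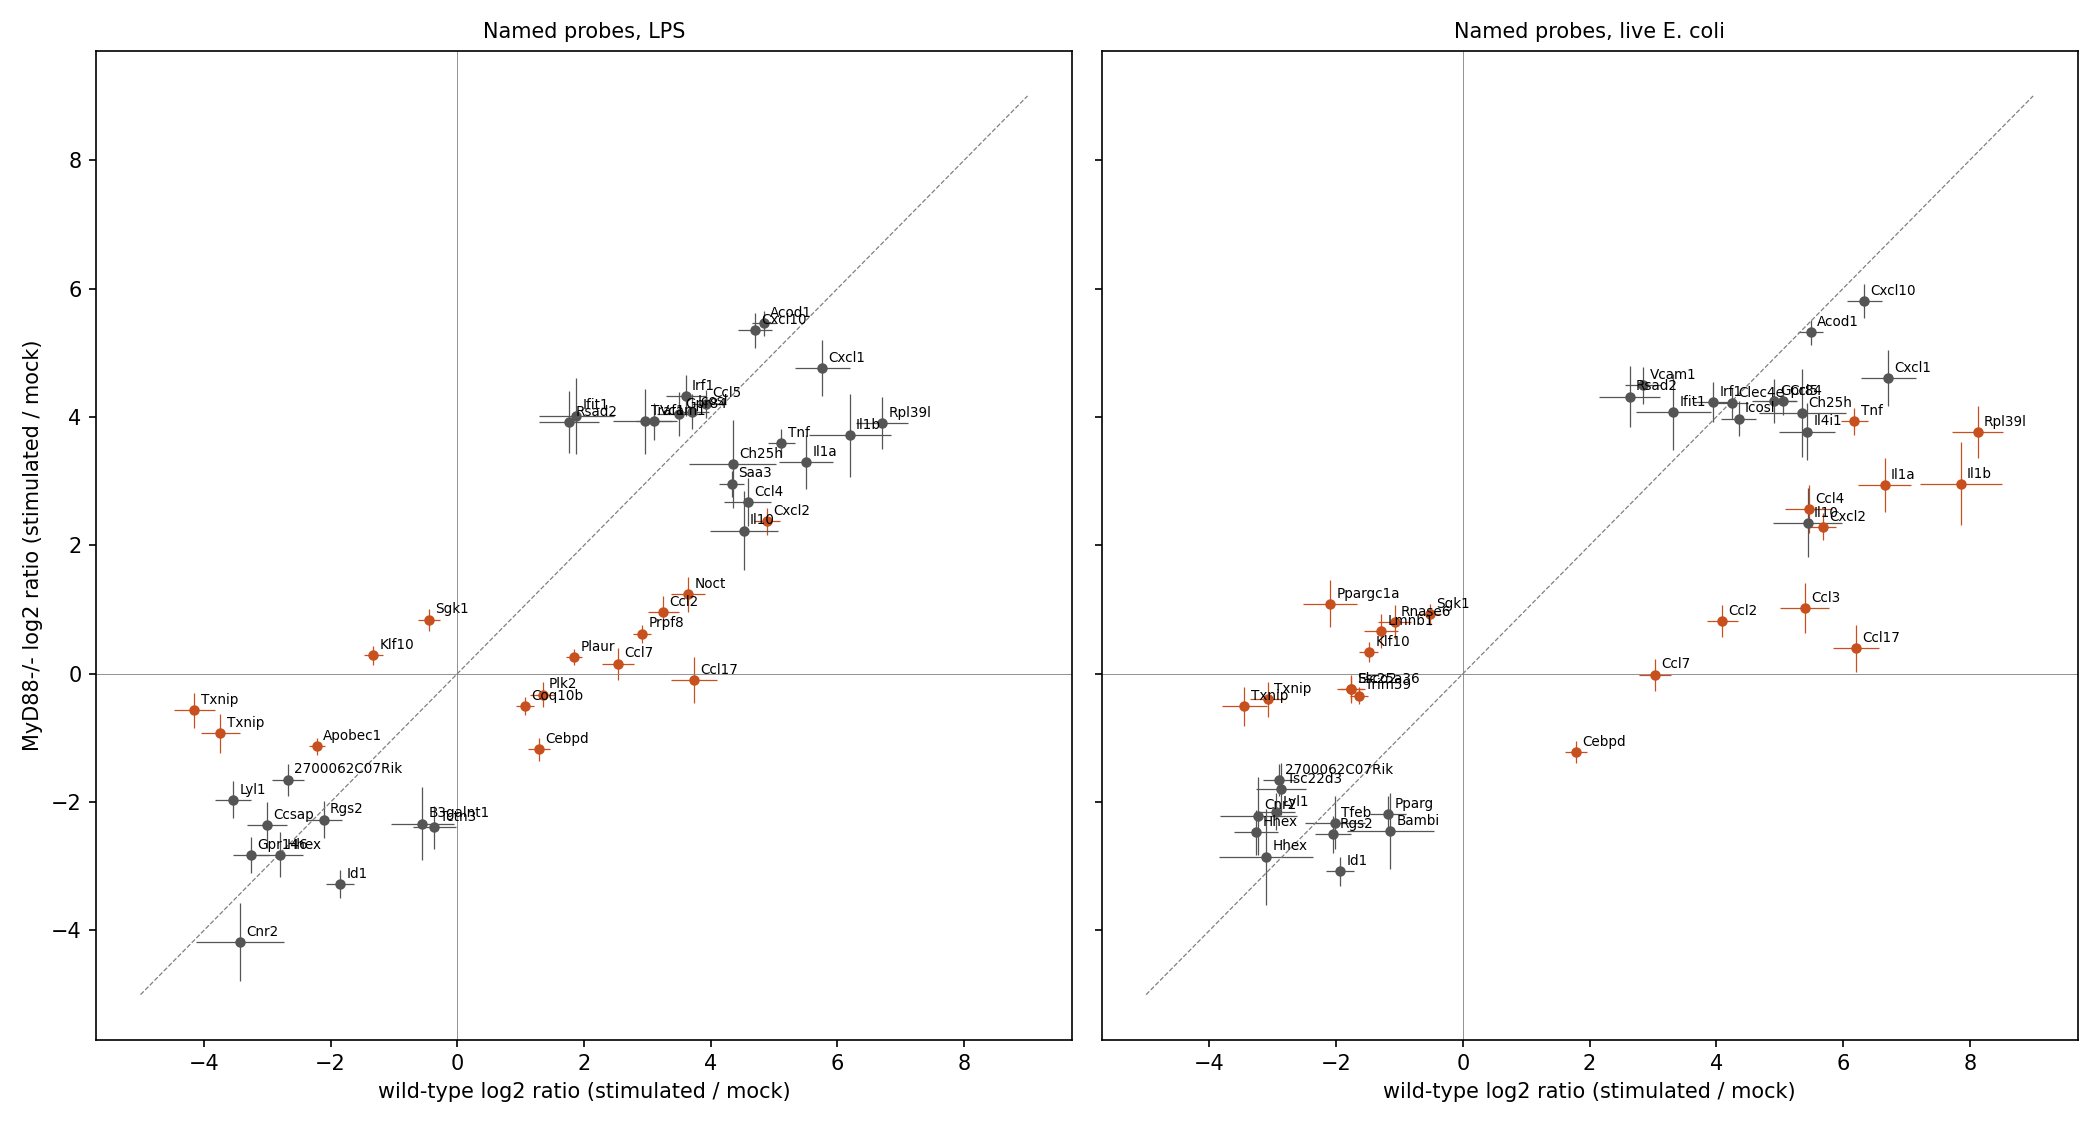
Log2 ratio in MyD88-/- cells (vertical axis) against wild-type cells (horizontal axis) for the probes with the largest changes by the rule for named genes, LPS and E. coli in separate panels, with standard errors of the fit. The dashed line marks equal ratios, and probes with a called genotype difference are orange, such as Ccl17 at 6.20 and 0.40 for E. coli.

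Whether live bacteria and LPS acted differently was compared within each genotype. A single dose of each was used, and whether the doses were equal in strength is not known. No gene was called, but lists of inflammatory genes were shifted upward with E. coli in wild-type cells. Cytokines had a median difference of 0.92 (adjusted p = 1.36e-05), chemokines of 0.82 (5.86e-08), immediate early genes of 0.34 (0.000105) and effectors of 0.30 (0.00127), all held with an estimated correlation. Interferon genes had a median of 0.51 (5.09e-10, but adjusted p = 0.0592 with an estimated correlation). NF-kB genes had a median of 0.25 (0.0429, but adjusted p = 0.469 with an estimated correlation, and 0.43, 0.275, 0.49 and 0.197 without wild-type LPS mouse 2 or 4 or wild-type E. coli mouse 2 or 3). Adjusted over the list alone, 2 chemokines were higher, and 1 gene each of the cytokine, interferon, immediate early and effector lists. In MyD88-/- cells interferon genes were higher with E. coli at 0.00675, but gave an adjusted p = 0.594 with an estimated correlation and 0.162 and 0.797 without MyD88-/- LPS mouse 3 and MyD88-/- E. coli mouse 2. B cell markers were also higher there at 0.0333, but gave an adjusted p = 0.0521 with an estimated correlation and 0.33 with the mouse as a block, and 0.0502 to 0.254 without MyD88-/- LPS mouse 1, 2 or 4 or MyD88-/- E. coli mouse 2, 3 or 4. The limma counts were 0 probes in wild-type cells, 297 at an unadjusted p under 0.05, and 0 in MyD88-/- cells, 177 unadjusted. With the mouse as a block, since the labels number the mice alike for both stimuli, limma again called 0, with 390 and 260 unadjusted.

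The genotype by stimulus interaction asks whether the genotype difference was larger with bacteria than with LPS. Cytokines, chemokines and immediate early genes had a more negative genotype difference with E. coli, with median interactions of -0.80, -0.84 and -0.38. The adjusted p were 0.000353, 8.57e-05 and 2.66e-05, and held with an estimated correlation. The interferon and NF-kB lists had medians of -0.24 and -0.21 (adjusted p = 0.0318 and 0.0245), and gave an adjusted p = 0.485 and an adjusted p = 0.343 with an estimated correlation. The interferon call ended without any 1 of 8 mice, namely wild-type LPS mice 3 and 4 (0.0961 and 0.153), MyD88-/- LPS mouse 2 (0.266), wild-type E. coli mice 1 and 2 (0.26 and 0.185) and MyD88-/- E. coli mice 1, 3 and 4 (0.118, 0.139 and 0.167), and the NF-kB call without any 1 of 7 mice, wild-type LPS mice 2 and 4 (0.119 and 0.122), MyD88-/- LPS mouse 2 (0.114), wild-type E. coli mice 2 and 3 (0.185 and 0.066) and MyD88-/- E. coli mice 1 and 3 (0.118 and 0.0824). No single gene was called by limma (0 of 7325 probes, 219 at an unadjusted p under 0.05, and 0 with the mouse as a block, 297 unadjusted).

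Both stimuli changed many of the same probes. In wild-type cells 471 probes rose with LPS and with E. coli and 485 fell with both, against 55.2 and 78 for independent calls, and none moved in opposite directions. Without MyD88 325 rose and 224 fell with both, against 24.6 and 15.2, with none opposite. Across probes, which are not independent replicates, the responses correlated with r = 0.832 (rho = 0.665) in wild-type and r = 0.791 (rho = 0.597) in MyD88-/- cells. Both ratios of a mouse may share 1 mock RNA, and simulated unchanged responses that share it gave r of 0.469 and 0.459. The simulation gives stimulated and mock RNA noise of equal size. Residuals of the same mouse number correlated only between -0.057 and 0.14, so the simulated r and covariance may overstate what sharing adds here. Responses taken from different mice, which cannot share it, gave r between 0.673 and 0.751 in wild-type and between 0.524 and 0.692 in MyD88-/- cells. These means rest on fewer mice, and their noise lowers r by itself. The covariance was 0.402 in wild-type and 0.267 in MyD88-/- cells. From different mice it was 0.39 to 0.421 and 0.248 to 0.276, against 0.0348 and 0.0345 in the simulation. The genotype differences for LPS and E. coli correlated with r = 0.43, against 0.464 in the simulation with a shared mock and between 0.168 and 0.31 from different mice. Their covariance was 0.112, against 0.0693 in that simulation and between 0.075 and 0.128 from different mice. A similar covariance was thus found where no mock could be shared.

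Genes outside the inflammatory lists were also called, and the examples given are from wild-type cells given LPS unless said otherwise. Of 26 lysosome and phagocytosis genes 12 fell and 2 rose with LPS and with E. coli in wild-type cells (16 and 13 fell adjusted over the list alone, and 2 rose), with the protease gene Ctsl at -0.99 and Lamp1 at -0.38. The list passed at 0.012 for LPS and 0.0168 for E. coli, but gave an adjusted p = 0.0839 and an adjusted p = 0.0935 with an estimated correlation, and the E. coli call ended at 0.0565 without wild-type E. coli mouse 1. Without MyD88 3 fell and 2 rose with LPS (0.0899) and 1 fell and 1 rose with E. coli (0.292), while adjusted over the list alone 7 fell and 2 rose with LPS and 1 fell and 2 rose with E. coli. The genotype difference of the list was not called for LPS (0.195, but 0.0418 without MyD88-/- LPS mouse 4) or for E. coli (0.0847). Of 22 antigen presentation genes 3, 6, 5 and 6 rose in wild-type LPS, MyD88-/- LPS, wild-type E. coli and MyD88-/- E. coli (3, 7, 5 and 9 adjusted over the list alone), led by the dendritic activation marker Cd83 at 3.02. That list passed at 0.0111, 0.000416, 0.00682 and 0.000234, but in wild-type cells gave an adjusted p = 0.125 for LPS and an adjusted p = 0.122 for E. coli with an estimated correlation. Of 15 glycolysis and hypoxia genes 4, 3, 3 and 4 rose and 1, 0, 1 and 0 fell, in the same order of groups (4, 4, 5 and 4 rose and 1, 1, 2 and 0 fell adjusted over the list alone), with the hexokinase gene Hk2 at 1.67. That list gave 0.0943, 0.0773, 0.0814 and 0.0266, the last of which passed (0.0205 with an estimated correlation) but was 0.134 without MyD88-/- E. coli mouse 1, and its E. coli genotype difference was not called (0.983). Of 21 cell death genes 6, 5, 5 and 5 rose and 1, 1, 4 and 2 fell (6, 5, 6 and 5, and 1, 1, 6 and 2, adjusted over the list alone), with the death receptor gene Fas at 3.67, and the list gave 0.0943, 0.108, 0.653 and 0.129. Of the 23 macrophage identity genes 1, 1, 2 and 2 rose and 1, 2, 2 and 2 fell (the same rises and 1, 2, 6 and 3 falls adjusted over the list alone), and the list gave 0.273, 0.672, 0.416 and 0.553.

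Among the remaining lists, the cell cycle inhibitor Cdkn1a rose by 2.03 at probe 13203 in wild-type cells given LPS, while probe 3569 gave 0.22 (adjusted p = 0.49). Of its list, 7 of 34 cell cycle genes fell and 1 rose with each stimulus in wild-type cells, while 2 fell and 2 rose with each in MyD88-/- cells (9, 2, 7 and 2 falls and the same rises adjusted over the list alone), with list values of 0.127, 0.814, 0.275 and 0.553 in the order used above. The genotype difference of the list was 0.00643 for LPS (adjusted p = 0.1 with an estimated correlation) and 0.731 for E. coli. Of 16 oxidative stress genes 5 fell and 3 rose in wild-type cells given LPS (5 and 3 adjusted over the list alone), with the haem oxygenase gene Hmox1 at -1.32 and the thioredoxin reductase gene Txnrd1 at 0.87, and the list gave 0.361, 0.645, 0.809 and 0.872. Of 16 sterol and lipid genes 3 fell and 1 rose there (4 and 2 adjusted over the list alone), with the lipid droplet gene Plin2 at -1.24, and the list gave 0.373, 0.837, 0.731 and 0.553. Of 48 ribosomal protein genes 1, 2, 1 and 1 rose, also adjusted over the list alone, and 1 fell in wild-type cells given E. coli (0 adjusted over the list alone), and the list gave 0.824, 0.999, 0.809 and 0.741. Rpl39l was 1 of these in each response, at 6.70 ± 0.40 in wild-type cells given LPS (adjusted p = 2.15e-08), the largest rise among all tested probes that met the rule for named genes. Of 10 housekeeping genes 3 fell with either stimulus in wild-type cells and none in MyD88-/- cells (4, 0, 4 and 0 adjusted over the list alone), with list values of 0.0997, 0.405, 0.192 and 0.87, and the genotype difference of the list was not called for LPS (0.353) or E. coli (0.106). Of 4 T cell markers 2 fell in each response and 1 rose in wild-type cells given E. coli (adjusted over the list alone 1 also rose with LPS), and the list gave 0.0943, 0.0715 and 0.0873 in the first 3 responses. Of 8 B cell markers 1, 3, 1 and 1 fell and 1 rose in MyD88-/- cells given E. coli (adjusted over the list alone 1 also rose in MyD88-/- cells with LPS), and the list gave 0.937, 0.0899 (0.0332 without MyD88-/- LPS mouse 3), 0.898 and 0.741, with the B cell adaptor gene Blnk at -0.69. Markers of neutrophils (0.937, 0.999, 0.809 and 0.882), dendritic cells (0.529, 0.807, 0.809 and 0.553), erythroid cells (0.72, 0.645, 0.688 and 0.824) and stromal cells (0.644, 0.999, 0.416 and 0.592) were not called as lists in any response.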

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

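The tests of explanations and the counts of other splits in this part were chosen or worded only after the results were seen, while the comparisons between groups were planned. A mouse stands apart here where its gap to the nearest of the other 3 mice took most of the range of its group. Chance does this to about 1 in 20 groups, and it occurred in 16 of 344 groups of single genes and in 5 of 92 groups of list means. In MyD88-/- cells given LPS, mouse 4 stood apart for Ccl4 (log2 ratio 0.861) and Il1rn (0.871), mouse 3 for Ifnb1 (1.49) and mouse 2 for 2700062C07Rik (-2.06). In wild-type cells given E. coli, mouse 1 stood apart for Ccl4 (6.26) and 2700062C07Rik (-4.28) and mouse 4 for Cxcl2 (5.91). In MyD88-/- cells given E. coli, mouse 1 stood apart for Hhex (-1.84) and Fas (1.62), mouse 4 for Il1a (4.52) and mouse 2 for Irf7 (2.11). In wild-type cells given LPS, mouse 1 stood apart for Slc25a36 (-1.17) and Socs1 (2.88), mouse 2 for Blnk (-0.473), mouse 3 for Cd28 (-1.29) and mouse 4 for Cxcl14 (-1.73). Among list means, MyD88-/- E. coli mouse 2 stood apart for interferon genes (2.28), wild-type E. coli mouse 2 for Toll-like receptor components (0.499), wild-type E. coli mouse 1 for lysosome genes (-0.436), MyD88-/- LPS mouse 4 for ribosomal proteins (-0.0342) and wild-type LPS mouse 2 for erythroid markers (0.2).

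Responses that differed between the genotypes for LPS, by the test of the difference itself, were those of 21 probes over all tested and of 66 within the wild-type response. The named genes were higher in MyD88-/- cells by 3.58 and 2.81 for Txnip (probes 13525 and 6185), 1.62 for Klf10, 1.29 for the kinase gene Sgk1 and 1.08 for the RNA-editing enzyme Apobec1. They were lower with -3.84 for Ccl17, -2.51 for Cxcl2, -2.47 for Cebpd, -2.41 for Noct, -2.38 for Ccl7, -2.295 for Prpf8, -2.29 for Ccl2, -1.67 for Plk2, -1.58 for Plaur and -1.57 for Coq10b (probe 2571), whose other probe (7400) gave -0.0228 and -0.128 in the genotypes. The call of Sgk1 ended without wild-type LPS mouse 1 or 2 or MyD88-/- LPS mouse 1 or 4 (adjusted p between 0.0973 and 0.11) and that of Apobec1 without MyD88-/- LPS mouse 2 (0.0556). Lists that differed were cytokines (adjusted p = 1.61e-06), chemokines (1.48e-11), interferon genes (0.00164), immediate early genes (6.01e-06), effectors (0.0495), oxidative stress (0.0164), cell cycle (0.00643) and B cell markers (0.0164). With an estimated correlation the interferon, effector and cell cycle lists were not called (adjusted p = 0.409, 0.097 and 0.1). Further limits of these list calls stand with the LPS difference in the report.

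For E. coli the responses of 55 probes differed over all tested and of 228 within the wild-type response. Higher in MyD88-/- cells were the mitochondrial coactivator gene Ppargc1a (3.185), Txnip (2.95 and 2.68), the nuclear lamina gene Lmnb1 (1.95), the ribonuclease gene Rnase6 (1.88), Klf10 (1.82), Esco2 (1.53), Slc25a36 (1.52), Sgk1 (1.44), Trim59 (1.30) and Apobec1 (1.15). Lower were Ccl17 (-5.80), Il1b (-4.90), Ccl3 (-4.37), Rpl39l (-4.35), Il1a (-3.72), Cxcl2 (-3.39), Ccl2 (-3.28), Ccl7 (-3.05), Cebpd (-3.00), Ccl4 (-2.89), Noct (-2.82), Prpf8 (-2.75), Socs1 (-2.52), Mmp13 (-2.48), Tnf (-2.25), Saa3 (-2.21), Plaur (-2.07), Plk2 (-2.01), Coq10b (-1.54), Il1rn (-1.53), Id2 (-1.27) and Junb (-1.06). With wild-type and MyD88-/- E. coli mice given in that order, the call ended for Ppargc1a without mouse 1 or 4 and mouse 1, 2 or 4 (adjusted p up to 0.0782), for Lmnb1 and Rnase6 without mouse 2, 3 or 4 and mouse 1 or 4 (up to 0.0834 and 0.0842), and for Slc25a36 without mouse 1, 2 or 3 and mouse 1, 2 or 3 (up to 0.105). It ended likewise for Il1b without mouse 1 or 2 and mouse 1 or 2 (up to 0.0666), for Socs1 without any 1 of 13 mice (up to 0.13), for Ccl4 without wild-type mouse 1 (0.0597), for Il1rn without mouse 1, 2 or 3 and mouse 1, 3 or 4 (up to 0.0827) and for Mmp13 without mouse 1 or 2 and mouse 1 or 3 (up to 0.0642). Lists that differed were cytokines (2.15e-15), chemokines (6.54e-23), immediate early genes (6.45e-17) and effectors (0.000221). In the interaction they were cytokines (0.000353), chemokines (8.57e-05), interferon genes (0.0318), NF-kB genes (0.0245) and immediate early genes (2.66e-05). With an estimated correlation the interferon list gave an adjusted p = 0.485 and the NF-kB list an adjusted p = 0.343.

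Each comparison of groups was repeated over the 35 splits of its samples into groups of 4. For the interaction the numbered mice were split, with both ratios of a mouse number moving together. Equal numbers for both stimuli were thus taken as 1 animal, which the residuals did not show. For the probes called between genotypes no other split gave as many. There were 21 for LPS, at most 1 in another split, and 55 for E. coli, at most 0. The same held for the sorted wild-type calls, with 66 for LPS and 228 for E. coli and at most 6 in another split. In each of these 4 cases 1 of 35 splits, the real one, gave as many. That is the smallest share 35 splits can give, and several counts were judged, so it argues against chance without excluding it. Splits that mix genotypes also carry any real difference into the spread within groups, which lowers their counts. Every split reaches a count of 0, so for the 0 probes between stimuli and in the interaction the 35 of 35 splits say nothing about chance, the highest others being 3 in wild-type mice, 1 in MyD88-/- mice and 0 in the interaction. The number of lists called in the LPS difference (8, highest other 5) and in the interaction (5, highest other 1) was reached by 1 split each. These splits used the preset correlation. With an estimated correlation, which was not run over the splits, 5 and 3 lists were called. More than 1 split gave as many lists as the E. coli difference (4, highest other 6, reached by 9 splits). So it was between stimuli in wild-type mice (6, highest other 6, reached by 2) and in MyD88-/- mice (2, highest other 4, reached by 12). These last 3 counts do not argue against chance. A count of lists leaves out which lists passed and by how much, so it does not judge any single list. Among the 8 splits that part all 4 numbered pairs of a genotype, the highest other count of lists was 5 in wild-type and 2 in MyD88-/- mice.

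The smaller rises of cytokine, chemokine and immediate early genes without MyD88 were weighed against technical explanations. Ratios compressed alike on all MyD88-/- arrays would keep the ratio of interferon and NF-kB list means to the chemokine mean. Yet it was higher in MyD88-/- mice for both lists and stimuli, as with 0.859 ± 0.0423 (SD, n = 4) against 1.72 ± 0.278 for NF-kB genes with LPS. The highest of the 4 exact permutation p was 0.0286, the smallest that test can give. The ratio was chosen after the chemokine means had been seen to differ, so its p restates that difference and adds no separate support. Both ratios of a stimulus also share the chemokine mean. Dye orientation was unequal only with LPS, where MyD88-/- mouse 4 had no swapped array, and a bias from it is argued against by the mean differences of these 3 lists within a single orientation, which came to between 82.4% and 130% of those in the fit. Without that mouse 18 of the 21 LPS probes were still called, although unswapped arrays alone called only 11. A lower induction of these lists without MyD88 is a candidate explanation, as a hypothesis found and tested on the same data, while other differences between the genotypes, such as in the mock cells, remain untested.

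MyD88-/- LPS mouse 4 gave 7.21 for Il1b, where the other mice lay between 1.5 and 3.27, and 0.861 for Ccl4, where they lay between 3.13 and 3.40. Il1b lay toward the wild-type values and Ccl4 away from them. In this mouse Il1b did not meet the rule for standing apart, while Ccl4 and Il1rn (0.871) did. They are among the 16 of 344 groups, about as many as chance gives. An array of a wild-type mouse under this label is argued against by its score on the genotype signature of 53 probes, -0.331 against -0.309 ± 0.0658 (SD) in the other MyD88-/- and -0.992 ± 0.0826 in the wild-type LPS mice. Noise of a single array cannot be told apart from a difference between mice, since 0.857% of its probes lay at least 3 from the mean of the other mice, against 1.07%, 0.241% and 0.637% on the unswapped arrays of mice 1 to 3. The mean of neutrophil and granulocyte precursor markers was 1.43 in mouse 4, against -0.0973, 0.149 and -0.372 in mice 1 to 3. That of Toll-like receptor components was 1.02, against 0.267, 0.434 and 0.43, and neither list met the rule for standing apart there. No biological explanation was tested.

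The rise of the probe named Rpl39l, a ribosomal protein relative, was larger than that of any cytokine in wild-type cells given LPS. A spot artefact on some arrays is argued against by values above 0 on 31 of 31 arrays, and a general rise of ribosomal protein messages by a median of -0.0964 (SD 0.225) over the 47 others. A spot that reports another induced transcript stays open and cannot be told apart from a rise of Rpl39l, since its ratios correlated most with Saa3 over all probes (r = 0.95) and with Ccl17 among cytokines and chemokines (r = 0.946, both over 16 ratios, which fall into groups), neither closely enough to equal it. No biological explanation was tested.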

How the results depend on the processing

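No called value of a named gene or a list changed sign, and no uncalled value gained a call with the opposite sign. Sign changes of values that stayed uncalled were not counted. The majority of the wild-type LPS calls did turn, from 585 higher and 662 lower to 643 and 581 with centring, 602 and 524 with scaling, 353 and 300 in a fit on these mice alone and 327 and 153 at 2-fold, and that of the wild-type E. coli calls, 691 and 863, to 470 and 378 and to 352 and 209 in the latter settings. Each alternative covers only the results it can give. Lists were not run with a dye term, unswapped arrays, scaling, other filters or another variance prior, and some named genes have no value under stricter filters. Limiting the test to 2786 probes with a value on all arrays gave 39 probes for the LPS and 126 for the E. coli genotype difference, with fewer probes tested. Values in at least 2 mice of every group (8923 probes) gave 1 probe for wild-type E. coli minus LPS. A dye term with a random block gave 42 and 189 for the genotype differences and 363 for the sorted wild-type E. coli calls. Unswapped arrays alone (5725 probes) gave 12, 24 and 61 for these, with fewer arrays. A fit on the groups of a comparison alone gave 653, 417, 848 and 436 for wild-type LPS, MyD88-/- LPS, wild-type E. coli and MyD88-/- E. coli and 32 for the E. coli difference, with fewer mice behind the spread. A change of at least 2-fold, a stricter threshold by construction, left 480, 346, 561 and 362, and 113 sorted E. coli calls. Of the alternatives chosen after seeing the data, keeping the floor as a value left 959 of 968 values of named genes on their side of the threshold, while 8 lost and 1 gained a call. Of 207 list values 202 stayed, 3 lost and 2 gained a call. Leaving out the array with the widest spread gave 149 sorted E. coli calls. The own-group fit with its own filter gave 375, 255, 587 and 276, and 4 and 23 for the genotype differences. Sorting the calls of the MyD88-/- response instead, also added, gave 47 for LPS and 87 for E. coli, from another set of probes. The interaction needs all groups, so it has no such fit. Where no construction is named, the cause was not tested.

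Leaving out each mouse in turn gave 854 to 1360 for wild-type LPS, 497 to 787 for MyD88-/- LPS, 1115 to 1630 for wild-type E. coli and 510 (without MyD88-/- E. coli mouse 2) to 837 for MyD88-/- E. coli. The LPS difference ranged from 18 to 26 and the E. coli difference from 35 (without wild-type E. coli mouse 1) to 55, with 36 without MyD88-/- E. coli mouse 1. The sorted calls ranged from 40 (without MyD88-/- LPS mouse 4) to 98 for LPS, with 41 without mouse 1, and from 134 (without MyD88-/- E. coli mouse 4) to 242 for E. coli, with 139 and 146 without mice 1 and 2. The stimulus comparisons and the interaction stayed at 0 in limma, beside 297, 177 and 219 at an unadjusted p under 0.05. Lists called ranged from 53 to 60, a check added for lists after seeing the data. With the mouse as a block, for lists also chosen after seeing the data, B cell markers in MyD88-/- E. coli minus LPS went from an adjusted p = 0.0333 to 0.33, and leaving out single mice gave up to 0.254. Of 11086 values of named genes under 13 settings 10605 kept their side of the threshold, 379 lost and 102 gained a call, and of 15488 without 1 mouse these were 15192, 253 and 43. Of 1104 list values under 6 settings 1068 kept it, 31 lost and 5 gained it, and of 3312 without 1 mouse these were 3245, 41 and 26. The files hold no signal over background, so what weak spots limit is not known.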

Other observations

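Several textbook LPS genes had too few values for the test of all groups, and fits with a filter for 1 comparison, chosen after the data were seen, give their size. In wild-type cells given E. coli the prostaglandin synthase gene Ptgs2 rose by 6.72 ± 0.35 (SE, adjusted p = 0.000869, limma), Il6 by 4.84 ± 0.46 (adjusted p = 0.00501), the interleukin 12 subunit gene Il12b by 4.78 ± 0.42 (adjusted p = 0.0041), Csf2, a myeloid growth factor gene, by 4.05 ± 0.40 (adjusted p = 0.00537) and Nos2 by 2.05 ± 0.42 (adjusted p = 0.0488). With LPS the values were 6.10, 3.65 and 4.08 for Ptgs2, Il6 and Il12b (adjusted p = 0.0296, 0.043 and 0.0115), and 2.95 and 3.35 for Nos2 and Csf2, which were not called (adjusted p = 0.0981 and 0.0629). In MyD88-/- cells given E. coli Ptgs2 stood at 1.37 (adjusted p = 0.456), Il12b at -0.04 (adjusted p = 0.989), Nos2 at 0.45 (adjusted p = 0.278) and Cd14, the LPS co-receptor gene, at -0.43 (adjusted p = 0.37). The inhibitor gene Nfkbia stood at -0.02 in wild-type cells given E. coli (adjusted p = 0.985). The genotype difference was -5.35 ± 0.84 for Ptgs2, -4.82 ± 1.11 for Il12b and -1.59 ± 0.49 for Nos2, none of them called (adjusted p = 0.0622, 0.198 and 0.289). The interferon-induced Gbp2b rose in MyD88-/- cells by 3.59 ± 0.42 with LPS and 4.61 ± 0.54 with E. coli (adjusted p = 0.0349 and 0.0167).

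How often a spot carried a value also differed between genotypes for some of these genes. Il6 had a value on 14 of 16 wild-type and 3 of 15 MyD88-/- arrays, Csf2 on 14 and 4, and Gbp2b on 2 and 13. Of 13872 probes, 7 had values on a share of at least 0.75 of wild-type and at most 0.35 of MyD88-/- arrays. The reverse held for 18, among them Gbp2b, Ifna11 (4 and 12), Wnt2 (4 and 12) and Sst (5 and 12). Values at the floor counted as absent. These probes were picked after their values were seen, the spot filter is not stated, and the difference was not tested.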
